A study of Caenorhabditis elegans with 4 samples.

How the data were processed

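RNA was measured in synchronized first-stage (L1) larvae of the nematode Caenorhabditis elegans. Per the labels' protocols, parents were grown on bacteria carrying an RNAi plasmid for 60 to 65 h at 20 °C, their embryos were released with hypochlorite, hatched in buffer without food for 18 h and refed the same bacteria for 2 h 30 min. Total RNA was purified from Trizol lysates with DNase treatment, and 5 µg entered the ScriptSeq Complete Gold kit, which depletes ribosomal RNA and does not select poly(A). The 4 libraries fall into 2 groups of 2: wild type (strain N2) on the empty RNAi vector L4440, and a strain mutant for met-1 (GW1183) on RNAi against mes-4. The series text describes the 2 replicates of each group as independent biological replicates.

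The authors deposited a table of raw counts per gene for 20392 WormBase gene identifiers, with the length of each gene model, and a table of normalized log2 values for the same genes. The genome build ce10 is named per the submitters' processing notes. The aligner, the counting program, the gene annotation and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes (F-box, MATH, PALS, collagen and histone genes among them) may therefore be shared or lost in a way that cannot be told from the tables. In the deposited log2 table every value equalled log2(count × factor + 8), with 1 factor per library from 0.887 to 1.07 that brought each library to the same total. This was worked out from the values themselves, since no header states it. Every per-sample column was used.

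Total counts were 33272359 and 32593317 in wild type replicates 1 and 2, and 29081819 and 35106597 in met-1 mes-4(RNAi) replicates 1 and 2. At the lowest of these totals, a gene at 5 CPM (counts scaled to the library total) rests on 145 reads, a counting error of 8.3%, against a biological coefficient of variation of 22.1% over all genes in the edgeR model. Symbols for 19182 identifiers, chromosomes and relative positions along them came from the Ensembl annotation of assembly WBcel235. Because that assembly is not the build the authors used, no coordinates are printed. No GC content check was made, since no genome sequence was used here.

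Counts were analysed in R 4.3.3. Genes were filtered with filterByExpr of edgeR 4.0.16, which left 15008. Libraries were scaled by TMM, with factors from 0.962 to 1.04. The main test was edgeR's quasi-likelihood F-test (glmQLFit and glmQLFTest) without a block, with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are met-1 mes-4(RNAi) against wild type from this fit, and the standard error is the fold change divided by the square root of F. CPM values are given as mean ± SD over the 2 libraries of a group. Lists with at least 5 tested genes were tested with camera (limma 3.58.1), adjusted over 47 lists. It was run on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. When the correlation is estimated instead, camera also uses the few residual degrees of freedom of the 4 libraries. A higher p in that fit therefore does not measure correlation alone. The 49 lists of symbols and name patterns, the tests, the rule for named genes and 18 of the alternatives were fixed before the data were examined. Chromosomes were compared by camera and by Fisher's exact test on called genes, two-sided, adjusted over 12 tests. The figures were drawn with matplotlib 3.10.9.

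The rule for named genes took met-1, mes-4 and the other members of the list on H3K36 methylation. It also took the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, and up to 3 members per list with the smallest adjusted p. Because edgeR called no gene, the rule was applied to the calls of DESeq2 1.42.0, the second count test listed beforehand (Wald test, no shrinkage, default independent filtering). This step was chosen after the edgeR count was seen. DESeq2 left the adjusted p of 291 genes as NA, and these were not counted as calls.

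The procedure was tested on simulated data before use. Counts were drawn for the 15008 genes from the observed means, library sizes and dispersions, with 200 genes of at least 5 CPM changed in this comparison. edgeR recovered 49% of the genes changed 2-fold and 96% of those changed 4-fold, and DESeq2 recovered 68% and 98%. Of the simulated calls, 13.2% of edgeR's and 23.5% of DESeq2's were genes that had not been changed, above the nominal level for both tools. A simulated shift of 0.5 (log2) in the proteasome list was recovered by camera, and none of the other 46 lists was called (0 calls). Genes and libraries were drawn independently of each other. In the data the estimated correlation between genes of the proteasome list was 0.567. The simulation therefore does not show how often camera calls unchanged lists of correlated genes. Nor does it give the share of unchanged genes among the calls made in the data.

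Alternatives were other scalings (median-ratio size factors, upper quartile, library size only), no filter (at least 1 count), a filter of 5 CPM in 2 libraries, DESeq2, limma-voom, limma on the authors' normalized values, a replicate block, leaving out each library, leaving out the 20 most abundant genes, a fold minimum of 1.5 (glmTreat), an estimated correlation between genes or fry for the lists, and chromosome ends of 33% for the arms. After the data were seen, edgeR with bias-adjusted deviances, an adjusted p of 0.1, and DESeq2 under other scalings, without a filter, with a block and without each library were added.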

Results

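The series compared the transcriptomes of wild type L1 larvae and of L1 larvae in which methylation of histone H3 at lysine 36 (H3K36) was to be depleted. The mark itself was not measured in the data used here. In C. elegans it is placed by the methyltransferases MET-1 and MES-4, and larvae of the second group carried a met-1 mutation and were raised on RNAi against mes-4. They are called met-1 mes-4(RNAi) larvae here. Each group had 2 libraries, with totals of 32593317 to 33272359 counts in wild type and 29081819 to 35106597 in met-1 mes-4(RNAi) larvae. Genes detected per library numbered 17581 and 17884 in wild type and 18108 and 18397 in met-1 mes-4(RNAi) larvae, without overlap. The highest number came from the library with the lowest total. The 20 most abundant genes took 12.05% to 13.1% of the counts, and mitochondrial genes 6.44% to 8.32%, with overlap between the groups for both shares.

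The first question was whether the targeted transcripts were lower. The met-1 transcript (WBGene00016603, chromosome I) was at 168.4 ± 4.96 CPM (SD, n = 2) in wild type and 113.1 ± 2.47 CPM in met-1 mes-4(RNAi) larvae, 32.8% lower, a log2 fold change of -0.57 (SE 0.10). The mes-4 transcript (WBGene00003222, chromosome V) was at 35.8 ± 2.18 and 27.3 ± 1.48 CPM, 23.9% lower, a log2 fold change of -0.39 (SE 0.13). For both genes the 2 groups did not overlap. The edgeR adjusted p was 0.111 for met-1 and 0.267 for mes-4. DESeq2 called met-1 (adjusted p = 0.0039) and not mes-4 (adjusted p = 0.337). Over the unblocked alternatives the adjusted p ranged from 0.0039 to 0.436 for met-1 and from 0.267 to 0.719 for mes-4. Reads from a mutated transcript, or from the RNA fed to the larvae, are not separated from intact transcript in counts per gene.

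The remaining members of the H3K36 list did not pass either test. The log2 fold change was -0.21 for the demethylase gene jmjd-2, -0.24 for the demethylase gene jhdm-1, 0.16 for mrg-1, which encodes a chromodomain protein, and -0.02 for lin-59, an ASH1-type methyltransferase gene. The sign for lin-59 turned with the scaling. Of the 6 members, edgeR adjusted over the list alone passed 1, met-1 itself, lower, against 0 over all genes. The list as a set had a median log2 fold change of -0.23 and a camera adjusted p of 0.0917. The set includes the targeted genes met-1 and mes-4, so its direction was partly given by the design.

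**Figure D1:**
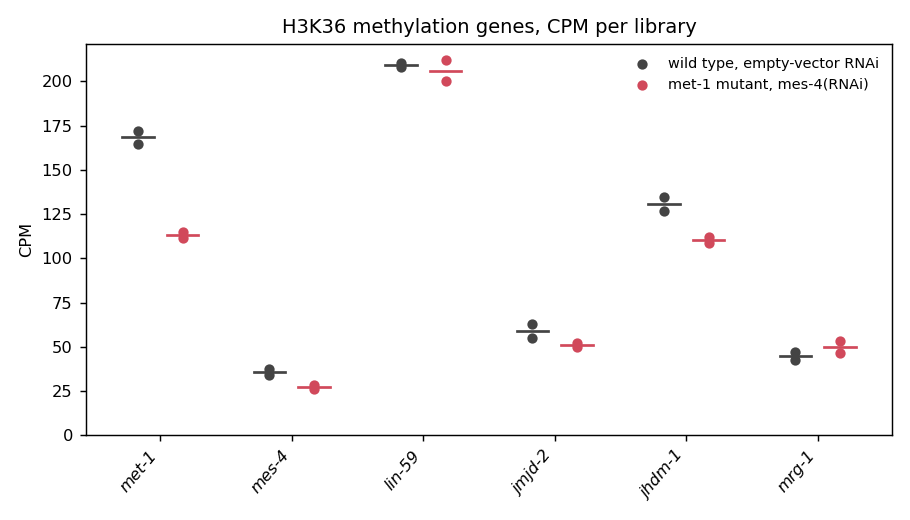
CPM per library (linear axis from 0) of the 6 genes of the H3K36 list in wild type and met-1 mes-4(RNAi) larvae. Points are libraries, 2 per group, and lines are group means. For met-1 the wild type libraries lie near 168.4 CPM and the others near 113.1 CPM, without overlap.

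The second question was which genes differed between the groups. The genes with the lowest p included genes at a low level in wild type that were higher in met-1 mes-4(RNAi) larvae, such as pgp-8 and cyp-34A6. They also included germline small RNA factors that were lower, such as drh-3. These calls were made by DESeq2 and not by edgeR. With edgeR's quasi-likelihood test no gene reached an adjusted p under the threshold (0 higher and 0 lower of 15008), the smallest adjusted p being 0.0556. It called 88 higher and 40 lower without a filter, 2 higher with a filter of 5 CPM in 2 libraries, and 24 higher and 3 lower without met-1 mes-4(RNAi) replicate 1. At an unadjusted p under 0.05, edgeR counted 2185 genes (1162 higher, 1023 lower), against 750 expected by chance if no gene differed. DESeq2 called 655 genes on the same counts, 367 higher and 288 lower. limma-voom called 0, and limma on the authors' normalized values called 0. All 655 DESeq2 calls had an unadjusted edgeR p under 0.05, and in all 655 the groups did not overlap. Non-overlapping groups occurred in 44.9% of all tested genes, against 33.3% by chance. Both chance values, 750 genes and 33.3%, assume libraries that deviate independently. Libraries of the same replicate number deviated together across genes (correlation 0.646), so neither value is a firm reference. In what follows, "rose" and "fell" are used of DESeq2 calls, while log2 fold changes are from edgeR.

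The risen genes had a median fold change of 3.22 and a median expression of 5.65 CPM over the 4 libraries, and the fallen genes a median fold change of 1.75 and a median of 30.72 CPM. The median of all tested genes was 12.33 CPM. At least 2-fold changes made up 291 of the rises and 84 of the falls. In simulated counts of this comparison, 23.5% of DESeq2's calls were unchanged genes. The simulation fixed the number of changed genes and drew genes and libraries independently. In the data, the replicate differences of both groups correlated across genes at 0.646. The simulated share therefore does not carry over to the calls counted here, and their share of unchanged genes is not known. Leaving out any library lowered the count of calls by more than 1.5 times. DESeq2 called 149 higher and 49 lower without wild type replicate 1, 113 and 38 without wild type replicate 2, 130 and 81 without met-1 mes-4(RNAi) replicate 1, and 101 and 75 without met-1 mes-4(RNAi) replicate 2.

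The largest rises under the rule were led by C49F5.6 (log2 fold change 3.47, from 2.56 ± 0.69 to 28.5 ± 6.03 CPM), C53A5.9 (3.43), C38D9.2 (3.20) and cyp-34A6 (3.13, from 2.18 ± 0.16 to 19.1 ± 0.28 CPM), which encodes a cytochrome P450. Next came F19B10.4 (3.04), pgp-8 (3.01, from 3.57 ± 0.04 to 28.7 ± 1.72 CPM), which encodes a P-glycoprotein transporter, and F15D4.5 (2.90). T28A11.2 (2.75), R03H10.6 (2.34) and amt-1 (2.33), an ammonium transporter gene, completed them. T28A11.2 differed between the 2 met-1 mes-4(RNAi) libraries, at 13.5 and 34.2 CPM. These 10 genes had edgeR adjusted p of 0.0556 to 0.102 and DESeq2 adjusted p from 9.48e-34 to 9.65e-08. Of these rises, 4 were on chromosome V and 3 on X.

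The largest falls were of ZK218.5 (-3.83), ZC434.8 (-2.60), trmt-10C.1 (-2.29, from 11.4 ± 1.90 to 2.32 ± 0.21 CPM), Y57G11C.36 (-1.85) and mex-6 (-1.85), which encodes an RNA-binding protein of the early embryo. They were followed by ZK973.1 (-1.81), Y48G1A.1 (-1.79), vkmt-1 (-1.74), F59A3.2 (-1.68) and tyms-1 (-1.64, from 30.1 ± 3.08 to 9.67 ± 0.94 CPM), the thymidylate synthase gene. ZK218.5 rested on wild type replicate 1, at 18.99 CPM against 2.39 CPM in wild type replicate 2. The edgeR adjusted p of the 10 was 0.0556 to 0.238 and the DESeq2 adjusted p 1.84e-10 to 0.0197. Of these falls, 6 were on chromosome I and 0 on X.

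**Figure D2:**
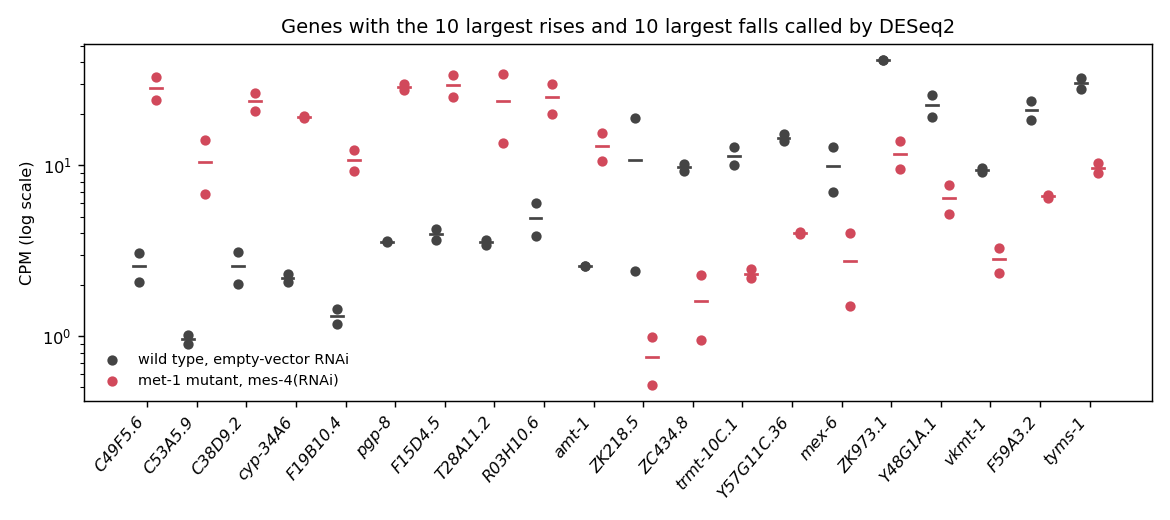
CPM per library (log axis) of the genes with the 10 largest rises and the 10 largest falls among DESeq2 calls of at least 5 mean CPM. Points are libraries, 2 per group, and lines are group means. The groups do not overlap for any of these genes, and ZK218.5 shows the widest spread within wild type.

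Genes of germline small RNA pathways were lower as a group. Of 32 tested members, 11 fell and 0 rose, and 30 had a negative log2 fold change. Adjusted over the list alone, 13 were lower by DESeq2 and 13 by edgeR. The falls included drh-3, a Dicer-related helicase gene (-1.33, from 68.2 ± 3.18 to 27.2 ± 0.01 CPM, DESeq2 adjusted p = 3.05e-12), rrf-3, an RNA-dependent RNA polymerase gene (-1.20, 80.8 ± 4.86 to 35.2 ± 2.09 CPM), and znfx-1, a helicase gene of germ granules (-1.03, 115.8 ± 1.0 to 56.6 ± 2.95 CPM). The remaining 8 were rrf-1, prde-1, dcr-1, sid-1, prg-1, ekl-1, hrde-1 and nrde-2, with log2 fold changes from -0.50 (nrde-2) to -2.76 (prde-1). They are named because they are all the falls of this list, a choice made after their values were seen. Several of these genes, such as dcr-1 and sid-1, also act outside the germline. The list had a median of -0.48 and a camera adjusted p of 7.34e-11. With an estimated correlation the adjusted p was 0.55.

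Other lists of germline and dividing cells were lower with few single calls. The oogenesis and eggshell list had a median of -0.88, and all 24 tested members were below 0, but 1 fell, mex-6. The groups did not overlap for 14 of the 24, and between replicates 1 and 2 of the same group the list differed by a median of 0.71 in wild type and 0.89 in met-1 mes-4(RNAi) larvae, about as much as between the groups. Its camera adjusted p was 8.32e-06, and 0.761 with an estimated correlation. In the meiosis and synapsis list (33 tested, median -0.35) 1 member fell, him-18, a Holliday junction resolvase subunit gene (-0.71). The list's camera adjusted p was 2.08e-05, and 0.55 with an estimated correlation. In the list of DNA replication and cell division (49 tested, median -0.14) 1 member fell, spd-5, which encodes a centrosome scaffold protein (-1.17, from 205.2 ± 12.04 to 91.1 ± 3.59 CPM). The camera adjusted p was 0.00791, and 0.761 with an estimated correlation. It was 0.0867 without wild type replicate 2, 0.0984 without met-1 mes-4(RNAi) replicate 1 and 0.0897 with a filter of 5 CPM. Adjusted over the list alone, DESeq2 counted 1, 3 and 1 lower members in these 3 lists. The germ granule and germline identity list (30 tested, median -0.18) missed camera's threshold (adjusted p = 0.0584). In it 2 members fell, the Piwi gene prg-1 (-1.10, shared with the small RNA list) and car-1 (-0.57), and 2 were counted when adjusted over the list alone. Of 15 spermatogenesis genes, spe-41 rose (2.60, from 0.33 ± 0.12 to 2.00 ± 0.17 CPM) and fog-1 fell (-1.32), and the list was not called (camera adjusted p = 0.799).

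Several families that tend to lie in clusters in the genome were higher. PALS genes, a family expanded in nematodes with members known from the response to intracellular pathogens, had a median log2 fold change of 1.80. Of 30 tested PALS genes 14 rose and 0 fell (19 higher when adjusted over the list alone), among them pals-39 (2.65, from 1.21 ± 0.41 to 7.63 ± 0.49 CPM), pals-30 (2.87) and pals-33 (2.39). Of 196 F-box genes, whose products are substrate adaptors of ubiquitin ligases, 23 rose and 1 fell (29 and 2 adjusted over the list alone), with a median of 0.78. Examples are fbxa-24 (1.26, from 68.2 ± 5.04 to 162.9 ± 20.4 CPM) and fbxc-14 (3.50). The F-box gene that fell was fbxa-196 (-4.35, from 7.61 ± 1.87 to 0.37 ± 0.04 CPM). The camera adjusted p was 8.53e-12 for PALS and 4.45e-12 for F-box genes, and with an estimated correlation the adjusted p was 0.732 for each. Of 60 MATH and BATH genes 4 rose and 0 fell (4 adjusted over the list alone), including math-28 (3.06, from 0.74 ± 0.05 to 6.20 ± 0.65 CPM) and math-7, which had no count in wild type and 0.83 ± 0.33 CPM in met-1 mes-4(RNAi) larvae. Their camera adjusted p was 0.0152, and 0.732 with an estimated correlation. It was 0.0721 without wild type replicate 2 and 0.0752 without met-1 mes-4(RNAi) replicate 1.

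Detoxification genes were mostly higher, with some falls. Of 44 glutathione S-transferase genes 11 rose and 0 fell (12 adjusted over the list alone), with a median of 0.59. They included gst-24 (1.69, from 84.3 ± 25.7 to 271.7 ± 12.57 CPM), gst-21 (1.59) and gst-12 (1.02). Of 71 cytochrome P450 genes 5 rose and 0 fell (5 adjusted over the list alone), with a median of 0.52, led by cyp-34A6, cyp-34A8 (1.41) and cyp-34A5 (1.66). Camera gave an adjusted p of 9.01e-06 for the transferases and 8.66e-06 for the P450 genes, and with an estimated correlation the adjusted p was 0.723 and 0.748. In the oxidative stress and detoxification list 8 of 29 genes rose and 1 fell (9 and 2 adjusted over the list alone). Of the 8, 5 were transferases counted above, and nit-1, a nitrilase gene, was at 1.15. The fallen gene was gsto-1 (-0.81, from 133.3 ± 4.17 to 75.9 ± 17.7 CPM), named after its value was seen. It is a glutathione S-transferase gene of the omega class and was not among the 44 above. Of 64 UDP-glucuronosyltransferase genes 4 rose and 2 fell (6 and 4 adjusted over the list alone), with ugt-15 at 1.04, ugt-40 at 1.47 and ugt-12 at -0.69. The fallen ugt-12 was the more abundant, from 146.3 ± 7.41 to 90.4 ± 8.80 CPM. The risen ugt-15 went from 9.56 ± 0.93 to 19.6 ± 2.64 CPM and ugt-40 from 2.88 ± 0.76 to 7.95 ± 0.33 CPM. Camera gave these lists an adjusted p of 0.0334 and 0.0252, and with an estimated correlation 0.761 and 0.732 as adjusted p. The call of the oxidative stress list ended without wild type replicate 2 (adjusted p = 0.361) or met-1 mes-4(RNAi) replicate 1 (0.0984), and that of the UDP-glucuronosyltransferases without wild type replicate 1 (0.125) or met-1 mes-4(RNAi) replicate 1 (0.166). Both also ended with library size only (0.0754 and 0.055) and without a filter (0.0576 and 0.0574).

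Cuticle collagens were also higher, and the muscle and hedgehog-like lists passed camera only with particular libraries included. Of 82 collagen genes 7 rose and 0 fell (7 adjusted over the list alone), with a median of 0.57, among them col-103 (1.04, from 101.7 ± 26.7 to 208.4 ± 52.6 CPM), col-42 (0.89) and col-101 (1.78). Camera gave them an adjusted p of 1.73e-06, and 0.55 with an estimated correlation. Of 40 body wall muscle genes 2 rose (2 adjusted over the list alone), the myosin heavy chain gene myo-3 (1.26, from 350.1 ± 97.2 to 838.1 ± 332.0 CPM) and the calponin gene cpn-3 (1.15). For that list camera gave an adjusted p of 0.0315, and 0.777 with an estimated correlation. It was 0.688 without wild type replicate 1, 0.843 without met-1 mes-4(RNAi) replicate 2 and 0.1075 without a filter. Against a median of 0.162 between the groups (mean log2 CPM), the list differed between replicates 1 and 2 by -0.214 in wild type and -0.368 in met-1 mes-4(RNAi) larvae. Hedgehog-like genes (40 tested, median 0.36) had 0 calls, also when adjusted over the list alone. Their camera adjusted p was 0.0252, with 0.761 as the adjusted p under an estimated correlation, 0.559 without wild type replicate 2, 0.93 without met-1 mes-4(RNAi) replicate 1 and 0.0577 with library size only. Between replicates 1 and 2 they differed by 0.742 in wild type and 0.802 in met-1 mes-4(RNAi) larvae, against 0.337 between the groups.

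Chemoreceptor and nuclear hormone receptor lists passed camera with few single calls, and the antimicrobial list passed narrowly with 0. Of 411 chemoreceptor genes 3 rose (2 adjusted over the list alone), sru-27 (4.99, from 0.15 ± 0.08 to 5.02 ± 0.08 CPM), str-225 and srh-192, with a median of 0.18. Of 224 nuclear hormone receptor genes 3 rose (3 adjusted over the list alone), nhr-94 (1.48), nhr-152 (1.91) and nhr-57 (0.86), with a median of 0.13. In both lists the share of rises lay below that of all tested genes (367 of 15008). Camera gave each list an adjusted p of 0.0122, and with an estimated correlation the adjusted p was 0.732 for each. The chemoreceptor call ended without met-1 mes-4(RNAi) replicate 1 (adjusted p = 0.112). The receptor call also ended without that library (0.0752) or wild type replicate 2 (0.0727). Of 29 antimicrobial genes 0 were called, also when adjusted over the list alone. Their median was 0.40 and the camera adjusted p was 0.04997, with 0.761 as the adjusted p under an estimated correlation. The antimicrobial call ended without wild type replicate 2 (median 0.33) or met-1 mes-4(RNAi) replicate 1 (median 0.175). The call also ended under every other scaling, filter and limma fit and without the 20 most abundant genes (0.0502 to 0.1018).

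The respiratory chain and proteasome lists passed camera as slightly lower, but not in every fit that left out 1 library. Of 40 respiratory chain genes 2 fell (2 adjusted over the list alone), cox-15 (-0.82, from 48.1 ± 2.48 to 27.3 ± 1.67 CPM) and ucr-2.3 (-1.92), and 36 were below 0, with a median of -0.16. Of 33 proteasome genes 0 were called, also when adjusted over the list alone, while 31 were below 0, with a median of -0.13. The camera adjusted p was 0.00023 and 0.00747, and with an estimated correlation the adjusted p was 0.761 and 0.773. Both calls ended without wild type replicate 2 (medians of -0.062 and -0.041) or met-1 mes-4(RNAi) replicate 1 (-0.018 and -0.058). That of the proteasome also ended with a filter of 5 CPM (camera adjusted p = 0.0603). Between replicates 1 and 2 the medians (mean log2 CPM) differed as much as between the groups or more, by -0.223 against -0.16 for the respiratory chain and -0.13 against -0.126 for the proteasome.

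**Figure D3:**
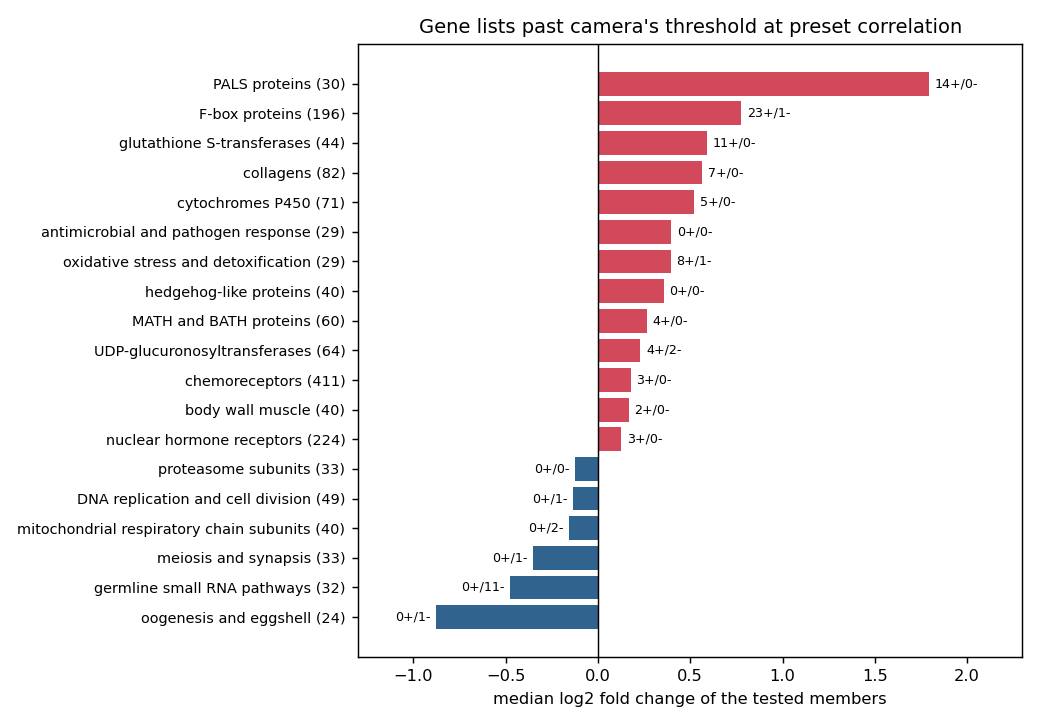
Median log2 fold change of the tested members (number in brackets) of the 19 gene lists past camera's threshold at the preset correlation. Labels give the members that rose (+) and fell (-) by DESeq2. PALS genes have the highest median, 1.80, and the oogenesis list the lowest, -0.88. None of the 19 lists passed with an estimated correlation, a fit that also uses fewer degrees of freedom.

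Markers of most other tissues did not pass camera as sets. The median log2 fold change was 0.03 for 47 neuronal genes, 0.09 for 39 cilia genes, 0.16 for 23 pharynx genes, 0.10 for 12 glial genes, 0.00 for 13 coelomocyte and excretory cell genes, -0.09 for 29 intestinal genes and 0.48 for 24 hypodermis and cuticle genes. The last of these depended on the scale, the median difference of mean log2 CPM being 0.007. Their camera adjusted p ranged from 0.171 (pharynx) to 0.852 (coelomocyte and excretory cells). Single members rose in 3 of these lists: osm-1 (0.64) among the cilia genes, phat-5 (1.19) among the pharynx genes and sulp-4 (1.22) among the excretory cell genes. Among heat shock genes hsp-16.2 (1.89, from 25.4 ± 9.36 to 94.0 ± 50.7 CPM) and hsp-16.41 (1.74) rose, and the mitochondrial chaperone gene hsp-6 fell (-0.60, from 1165 ± 47.5 to 767.1 ± 86.9 CPM). The camera adjusted p was 0.229 for the cytosolic heat shock list and 0.521 for the list of unfolded protein responses. The chromatin lists other than H3K36 (PRC2, H3K9, H3K4, dosage compensation, and DREAM with synMuv B repressors) had medians from -0.09 to 0.10, 0 DESeq2 calls and camera adjusted p from 0.312 to 0.873. Adjusted over the list alone, DESeq2 counted 1 higher and 1 lower gene among those of H3K4 and 1 lower among those of PRC2. The remaining lists with a camera test had adjusted p from 0.229 to 0.919. They include 114 C-type lectin genes, of which clec-52 (1.72) and clec-71 (1.62) rose and clec-53 (-1.09) fell, 25 molting genes, of which mlt-10 rose (1.21), and 26 fasting response genes, of which hacd-1 (1.16) and mtl-1 (1.78) rose. For the lists of dosage compensation, spermatogenesis, intestine, coelomocytes and excretory cells, unfolded protein responses, molting and ribosomal proteins the median, mean and camera direction differed in sign. Ribosomal protein genes (76 tested, median -0.01) and the reference genes (11 tested, median 0.01) had 0 calls, with camera adjusted p of 0.504 and 0.852.

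The third question was whether genes of the X chromosome and of the chromosome arms moved apart from the rest. The X was nearly free of falls. Of 2177 X-linked genes with a DESeq2 adjusted p, 4 fell (0.18%), against 2.28% on the other chromosomes, an odds ratio of 0.079 (Fisher's exact test, adjusted p = 1.74e-14). Those 4, named after their values were seen, were vap-1, R193.2, F11C7.2 and mrp-5. On the X 65 genes rose (2.99%), against 2.44% elsewhere (adjusted p = 0.165). Chromosome V held the most rises, 150 of 3141 genes (4.78% against 1.89% elsewhere, odds ratio 2.60, adjusted p = 4.27e-16). Falls were also less frequent on V (33 genes, 1.05% against 2.22% elsewhere, odds ratio 0.467, adjusted p = 1.93e-05). Rises were less frequent on I, III and IV, with odds ratios of 0.39, 0.30 and 0.51 and adjusted p of 1.34e-06, 1.19e-08 and 0.000156. Falls were most frequent on chromosomes I (74 genes, 3.38%, odds ratio 2.01, adjusted p = 2.94e-06) and III (81 genes, 3.72%, odds ratio 2.296, adjusted p = 1.32e-08). Genes are not independent replicates in these tests.

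Over all tested genes, the median log2 fold change of the X exceeded that of the autosomes by 0.09, with a camera adjusted p over the 6 chromosomes of 0.00466, and 0.0343 with an estimated correlation. Medians were 0.11 on V, -0.06 on I and -0.07 on III, with camera adjusted p of 0.00085, 0.00105 and 0.00085. With an estimated correlation, the adjusted p was 0.0995 for each of these 3. On II and IV the medians were 0.01 and -0.01, and camera made no call (adjusted p of 0.989 and 0.577). On the autosomes, the outer 25% at each end had a median above that of the central part by 0.08 (camera p = 0.0032, and p = 0.0231 with an estimated correlation). In the outer parts 207 of 4932 genes rose (4.20%) and 65 fell (1.32%), and in the central parts 91 of 7286 rose (1.25%) and 214 fell (2.94%). The odds ratios were 3.46 for a rise (Fisher's exact test, p = 1.51e-24) and 0.44 for a fall (p = 1.48e-09). Genes of the outer parts had a median expression of 9.05 CPM, against 16.21 CPM in the central parts. Whether expression level or gene families account for these odds ratios was not tested.

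**Figure D4:**
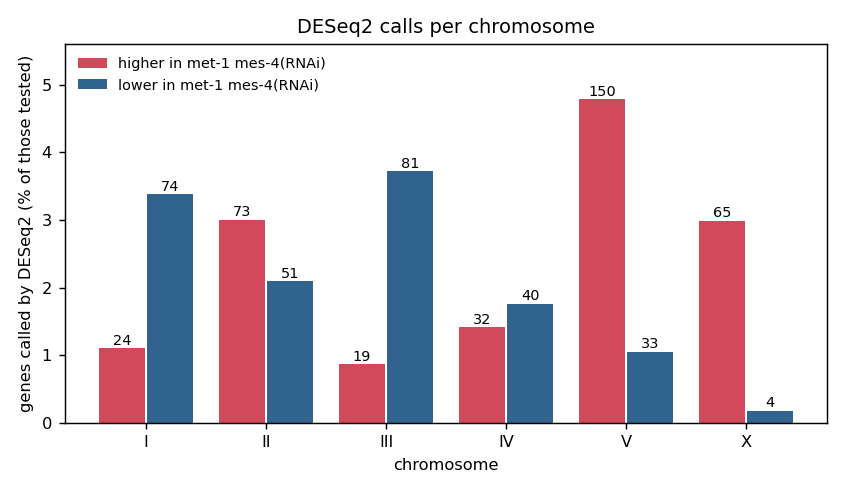
Percentage of the genes with a DESeq2 adjusted p on each chromosome that rose or fell in met-1 mes-4(RNAi) larvae, with the number of genes above each bar. Chromosome V has the highest share of rises (4.78%), and the X the lowest share of falls (0.18%).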

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

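DESeq2 with other scalings, without a filter, with a block and without each library, edgeR with bias-adjusted deviances, and an adjusted p of 0.1 were chosen after the data were seen. edgeR called 0 genes higher and 0 lower under every other scaling, without wild type replicate 1 or 2, without met-1 mes-4(RNAi) replicate 2, without the 20 most abundant genes and with a fold minimum of 1.5, as did limma-voom and limma on the authors' normalized values. The counts were 88 higher and 40 lower without a filter, 2 higher with a filter of 5 CPM in 2 libraries, 367 and 288 with DESeq2, 3 higher with bias-adjusted deviances, and 169 and 99 at an adjusted p of 0.1. Leaving out 1 library gave 0 to 24 higher and 0 to 3 lower, the 24 and 3 without met-1 mes-4(RNAi) replicate 1. DESeq2 called 101 to 149 higher and 38 to 81 lower when 1 library was left out. The cause of these differences was not tested.

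The met-1 log2 fold change was -0.57 in the main test and with DESeq2, which called it. Lists called higher numbered 13 at the preset correlation, 0 with an estimated correlation, 1 by fry (histones, adjusted p = 0.034) and 8 to 15 without 1 library (8 without wild type replicate 2 and 8 without met-1 mes-4(RNAi) replicate 1). Lists called lower numbered 6, then 0 with an estimated correlation and 0 by fry. Correlation alone does not account for all the losses under an estimated correlation. The estimates for the meiosis (0.00158) and collagen (0.00157) lists lay below the preset 0.01, yet camera's adjusted p was 0.55 for both. Most other called lists had estimates above the preset, among them oogenesis (0.776), respiratory chain (0.737), PALS (0.328), F-box (0.163) and P450 (0.156). For such lists the p at the preset correlation may be too small. Of the 19 lists, 8 held in every fit that left out 1 library: small RNA, oogenesis, meiosis, PALS, F-box, collagen, glutathione S-transferase and P450. These 8 also held under every other scaling, filter and limma alternative. The antimicrobial list lost its call under each of these and without the 20 most abundant genes (adjusted p 0.0502 to 0.1018). The oxidative stress list lost it with upper-quartile factors (0.0595), library size only (0.0754), no filter (0.0576) and the authors' values (0.0643), and the hedgehog-like list with the same 2 scalings and on those values (0.0525, 0.0577 and 0.0528). The UDP-glucuronosyltransferase list lost it with library size only (0.0550) and no filter (0.0574), the muscle list with no filter (0.1075), and the DNA replication (0.0897) and proteasome (0.0603) lists with a filter of 5 CPM. The median of the muscle list ran from -0.00020 (without met-1 mes-4(RNAi) replicate 2) to 0.34, and that of the hedgehog-like list from -0.0067 (without met-1 mes-4(RNAi) replicate 1) to 0.89. The X minus autosome difference was 0.074 without a filter, with an adjusted p of 0.0558, and stayed past the threshold otherwise. The difference between chromosome ends and centres passed under all its alternatives. The lin-59 value of -0.02 was 0.031 with upper-quartile factors, 0.029 with library size only, 0.0185 with a filter of 5 CPM, 0.027 on the authors' values, and -0.065 to 0.021 without 1 library.

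The replicate numbers are shared by the groups, but nothing says that they mark a shared day or batch, and 2 pairs are too few to decide. Across genes, the replicate 1 minus 2 differences of the 2 groups correlated at 0.646, and the second principal component (38.9% of the variance) parted the numbers. With the replicate number as a block, edgeR called 1540 genes higher and 1507 lower, met-1 (-0.57) and mes-4 (-0.39) included. All 655 DESeq2 genes were among them, with the same sign. DESeq2 with the block called 696 and 691. Of the 19 lists, the block ended the call of the oxidative stress list (adjusted p = 0.0506), and it added the germ granule and germline identity list to those called lower (adjusted p = 0.0385). Split by replicate number, the libraries gave 424 DESeq2 calls, and the crossed split gave 0. edgeR counted 1875 and 7 genes at an unadjusted p under 0.05, beside 2185 between the groups, which points to a structure of the libraries beside the group. At 5 CPM the counting error in the smallest library was 8.3%, below the coefficient of variation of 22.1% without the block and equal to the 8.3% with it, so depth would matter at that level if the block held.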

Other observations

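Yolk protein genes, normally expressed in the adult intestine, gave a small signal in these larvae. The gene vit-6 rose from 0.37 ± 0.02 to 4.04 ± 0.95 CPM (SD, n = 2; log2 fold change 3.43, DESeq2 adjusted p = 2.06e-07, edgeR adjusted p = 0.0578), and vit-1 rose from 0.34 ± 0.12 to 2.16 ± 0.49 CPM (2.66, DESeq2 adjusted p = 0.00524, edgeR adjusted p = 0.0924). The yolk gene vit-2 had 4 and 2 counts in wild type and 9 and 6 in met-1 mes-4(RNAi) larvae. The adult collagen gene col-19 had 2 and 0 counts in wild type and 2 and 5 in met-1 mes-4(RNAi) larvae. The yolk gene vit-5 had 0 counts in every library. The handling of reads shared by near-identical yolk genes is not given in the sources used here.

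Replicates 1 and 2 also differed. With the group in the edgeR model, 1558 genes were higher and 1142 lower in replicate 1. Among these genes, of those with at least 5 CPM that moved the same way in both groups, the ones with the 3 largest differences upward in replicate 1, picked after their values were seen, were ZK1053.4 (by 2.56 on the log2 scale in wild type and 3.96 in met-1 mes-4(RNAi) larvae), mlt-11 (2.39 and 4.12) and dpy-14 (2.38 and 3.89). The 3 largest downward were cpg-18 (-2.31 and -2.11), fat-7 (-1.39 and -2.43) and scl-6 (-1.86 and -1.59). Of the 47 tested lists, 15 passed camera's threshold between the replicates, each with an adjusted p of 0.847 under an estimated correlation. Of these, 8 were also called between the groups. The median difference between replicates was larger in size than that between the groups (both of mean log2 CPM) in 4 of the 8: hedgehog-like (0.918 against 0.337), muscle (-0.293 against 0.162), respiratory chain (-0.223 against -0.16) and proteasome (-0.13 against -0.126). It was smaller in oogenesis (0.884 against -0.906), F-box (0.342 against 0.722), P450 (0.365 against 0.543) and oxidative stress (0.183 against 0.415). The other 7 were ribosomal proteins (-0.34), neurons (-0.093), early embryo (0.768), patched-related proteins (0.267), heat shock (0.153), hypodermis and cuticle (1.464) and molting (0.207). Collagens had a median of 0.10 (adjusted p = 0.899), with 0.23 in wild type and -0.11 in met-1 mes-4(RNAi) larvae.

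In the tests below, those on chromosomes were set before their results were seen, and those on the replicates, the small RNA list and the oogenesis list only after the values they rest on were known. A candidate explanation for the difference between replicates is that the larvae of replicate 1 were younger or less well fed. The hypodermis and cuticle list was higher in replicate 1 in both groups, the smaller of the 2 medians being 1.10 on the log2 scale, but cuticle genes prompted the explanation, so this value does not decide it. Gene length does not account for the difference, since the correlation across genes of the 2 groups' replicate differences was 0.65 after a smooth trend on gene length was removed. A difference of stage or feeding and a batch of cultures or libraries shared by number both stay open, and the labels name no batch.

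The distribution of calls over the chromosomes was set against expression level, gene length and gene families. Within 10 bins of mean CPM the odds ratio of a fall on the X was 0.0811 (95% interval 0.0303 to 0.217), and within 10 bins of gene length it was 0.0715 (0.0266 to 0.192), so neither property accounts for the few falls there. For rises on chromosome V the odds ratio within 10 bins of mean CPM was 2.36 (1.91 to 2.92), and among the 12767 genes outside the fixed families it was 2.91 (2.26 to 3.73), so expression level and these families do not account for it as a whole. GC content was not tested, and gene clusters outside the fixed families stay open. No biological explanation was tested.

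The fall of germline small RNA genes may reflect fewer germ cells, or the difference seen between replicates. The germ granule and germline identity list, which fewer germ cells would also lower, lay 0.327 above the small RNA list in median log2 difference (-0.17 for 27 genes against -0.50 for 29, shared members left out, permutation p = 0.00157). Of 30 tested germ granule genes, 22 were below 0 and 8 above. The median log2 fold change was -0.88 for the oogenesis list, -0.48 for small RNA and -0.35 for meiosis. This order was not tested. Fewer germ cells would lower these lists alike only if germ cells gave each the same share of its RNA, which was not measured. The unequal medians therefore do not decide, and what part, if any, fewer germ cells had in the fall was not measured. Against the difference between replicates stands that the small RNA list moved by a median of -0.03 between replicate numbers. Its members' fall between groups exceeded the size of their replicate difference by 0.418 on average (permutation p = 2e-05). The list was chosen for its fall, so that excess was favoured in advance and adds no support. For the oogenesis list the same difference would move the hypodermis and cuticle list with it. On the scale of mean log2 CPM that list (median 0.007) lay 0.913 above the oogenesis list (-0.91) between the groups (permutation p = 1e-05). That p is the smallest that 100000 permutations can give. The hypodermis and cuticle list differed between replicates by 1.096 in wild type and 1.833 in met-1 mes-4(RNAi) larvae. Its median between the groups is thus uncertain, and this comparison does not decide. All these permutations moved genes or their signs, not libraries, so their p does not measure the spread between libraries. An effect of the genotype and RNAi stays open and untested, and the strain background, which differs with the group, is not separated from it.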
